A study of Mus musculus with 6 samples.

How the data were processed

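Dendritic cells were grown for 6 days from bone marrow of the 6-week-old Rag2 knockout mouse on a C57BL background, in medium with GM-CSF and IL-4 at 1.5 ng/ml each, per the labels' protocols. Rag2 is needed to assemble antigen receptors, so such mice lack mature T and B cells. The 6 samples fall into 3 groups of 2: unstimulated cells, cells in which reactive oxygen species (ROS) were generated by light, and cells given lipopolysaccharide (LPS), a component of the bacterial outer membrane sensed by Toll-like receptor 4. For the ROS group, hematoporphyrin, a light-sensitive porphyrin that makes ROS when illuminated, was given at 1 µg/ml for 1 h and washed out. The cells were then lit for 3 min by a light-emitting diode (450 to 600 nm, peak 515 nm, 3.1 mW per square cm) and cultured for 18 h. LPS was given at 1 µg/ml for 18 h. The labels do not say whether the unstimulated cells received hematoporphyrin or light, so the ROS group differs from them by the whole procedure. Nor is a time in culture after the 6 days recorded here for the unstimulated cells. Both treated groups may therefore also differ from them by 18 h of culture. Total RNA was amplified to biotin-labelled cRNA and hybridised to a 1-colour Illumina mouse bead array.

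The deposited table of probe signals holds the intensity of 25697 probes on a linear scale for each of the 6 arrays; it was made with GenomeStudio 2009.2 per the submitters' processing notes, and its background handling is not given in the sources used here. For 5 arrays the deposited table also gives a detection p-value per probe, in even steps of 1 in 798, as a rank among negative controls would give. The second LPS array has no detection p-value there. The authors' second table holds log2 intensities of 11220 probes that are quantile normalised, since each column has the same sorted values, with a median of 8.47. Its ranks equalled those of 1 array's signal in every column (100% of ranks). It lists each probe detected on at least 3 arrays and no other, counting a detection p under 0.05, and its values are not centred by gene. The base of the logarithm was read from the values.

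The detection limit of the array without detection p-values was recovered from the authors' table. Among probes detected on exactly 2 of the other arrays, those listed had signals on that array above 160.57 and those not listed had signals below 160.52. In simulated data this recovered 100% of the detection calls, an outcome given in advance because the simulated list of probes was made by the same rule. The background mean of that array was set at the share of probes that lay below the background mean on the other arrays, and its SD from the distance of the detection limit to that mean. This background estimate was repeated on each of the other arrays, with the detection limit still taken from its own detection p-values. The estimated background mean lay close to the one from its detection p-values, for example 143.33 against 144.02 for the first LPS array. The SD could differ more, for example 12.29 against 13.37 for the second ROS array.

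Signals were corrected for background with limma's normexp model, an offset of 16 was added, and the arrays were quantile normalised and put on the log2 scale. A probe was kept where its detection p was under 0.05 on both arrays of at least 1 group, which left 11622 probes. The platform annotation given for this work pairs 10558 probes of the authors' table with 1 gene symbol each, 0 with several and 662 with none. Of these, 10551 matched an Entrez gene of the RefSeq table of assembly GRCm38.p6, 7 did not and kept their symbol, and 0 symbols changed. Of the kept probes 10435 had a gene and 1187 were unnamed here, 535 of them because they are not in the authors' table. Each of 7897 genes was represented by its probe with the highest mean over the 6 arrays; 1897 genes had several probes. Coordinates are not given, because the build behind the probe design is not given in the sources used here.

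Groups were compared in R 4.3.3 with limma 3.58.1 (lmFit and eBayes), with 1 coefficient per group and no covariates. The 3 groups shared 1 estimate of the spread, with 3 residual and 3.02 prior degrees of freedom. P-values were adjusted by Benjamini-Hochberg over all 11622 kept probes within each comparison, and a gene was called changed at an adjusted p under 0.05. The 3 comparisons were ROS against unstimulated, LPS against unstimulated and LPS against ROS, and a positive log2 fold change means higher in the group named first. Errors of fold changes are standard errors from this fit. Where a gene was not above background on both arrays of a group, the fold is a bound, written as at least N-fold. It sets the mean of the brighter group against the mean, over the arrays of the dimmer group, of the higher of the lowest detected signal and the probe's own value. Where a gene was above background on 1 of the 2 arrays, the fitted fold is given with such a bound beside it.

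A total of 20 pathway lists and 8 cell type lists were written from textbook knowledge. The pathway lists cover NRF2 targets, antioxidant enzymes, heat shock, the unfolded protein and integrated stress response, p53 targets, inflammatory cytokines and chemokines, dendritic cell maturation, MHC class I, MHC class II, the type I interferon response, NF-kappaB feedback, immediate early genes, inducible effector enzymes, NADPH oxidase, glycolysis and hypoxia, the respiratory chain, cholesterol synthesis, heme metabolism, the cell cycle, and endocytic and pattern recognition receptors. The cell type lists cover type 1 and plasmacytoid dendritic cells, macrophages, neutrophils with their precursors, mast cells and basophils, natural killer cells, T and B cells, erythroid cells and stromal cells. A short list of sex-linked genes was kept as a check. Lists with at least 5 measured genes, 26 in all, were tested with limma's camera at a preset correlation of 0.01, with Benjamini-Hochberg over the lists of a comparison. Counts of list members rest on the adjustment over all kept probes, and the count adjusted over the list alone is given where it differs. Beside it, camera with an estimated correlation between genes and fry were run. With an estimated correlation, camera takes its p-values from the 3 residual degrees of freedom, whereas with the preset one it uses the number of genes.

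The genes named in the text came from a fixed rule. It took, per comparison, the 8 genes with the largest rise and the 8 with the largest fall among those past the threshold whose arrays did not overlap between the 2 groups, leaving out predicted loci and clone names. It also took the 2 members of each pathway list with the largest absolute fold and up to 2 more of a list described, and for cell type lists the 2 members with the highest mean and, where the list passed, the 2 with the largest absolute fold. A further 13 genes were to be given whatever their result: Hmox1, Nqo1, Gclm, Il12b, Il6, Tnf, Il1b, Il10, Cd40, Cd80, Cd86, Ccr7 and H2-Ab1; Il12b and Il10 are not named here because no kept probe carries their names. The groups, tests, lists and this rule were set before the data were examined, as were the alternative settings other than no normalization between arrays and a crossed pairing.

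The fit was tested on simulated data with known fold changes in 12297 probes. A log2 change of 2 was called with the right sign for 71.9% of changed probes in ROS against unstimulated, 70.3% in LPS against unstimulated and 78.9% in LPS against ROS. A log2 change of 1 was called for 9.09%, 1.52% and 25% of them. Unchanged probes made up 3.70%, 2.13% and 5.63% of the calls. In the simulation 12103 of the 12297 probes were unchanged in ROS against unstimulated, whereas the data gave 4569 calls among 11622 probes there. The adjustment is stricter where fewer probes change, so these shares do not carry over to the data. The number of arrays limits the precision. Alternatives covered the background correction, scaling between arrays, the authors' processed values, the filter on dim probes, the replicate number as a block, the variance model, the samples in the fit, a fold threshold, the counting of probes, and each array left out in turn.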

Results

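Gene expression was measured in mouse bone-marrow-derived dendritic cells left unstimulated, exposed to ROS generated inside the cells by light and hematoporphyrin, or stimulated with LPS, with 2 arrays per group. The study asked how ROS made on demand by light alter dendritic cells, with LPS as a second stimulus. The mean raw signal was 735 ± 43.1 on the unstimulated arrays, 634 ± 11.5 on the ROS arrays and 537 ± 11.2 on the LPS arrays (SD, n = 2 each). Detected probes numbered 11311.5 ± 62.9, 11344.5 ± 132.2 and 10456.5 ± 40.3 of 25697 in the same order, so that the LPS arrays were the dimmest and detected the fewest. Replicate arrays correlated across probes at r = 0.993 in the unstimulated, 0.992 in the ROS and 0.988 in the LPS group, while the highest correlation between arrays of different groups was 0.939. Probes are not independent replicates. The first principal component, with 66.3% of the variance, set the LPS arrays apart from the other arrays, and the second, with 27.2%, set the ROS arrays apart from the unstimulated ones. Nothing in the labels says that the replicates came from separate cultures or animals, so the p-values measure only the spread between these samples, which may be technical.

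The first comparison asked what the ROS procedure changed 18 h after illumination. After ROS 25 of 31 interferon genes and 17 of 23 maturation genes rose, while 17 of 20 glycolysis and hypoxia genes, 13 of 16 MHC class II genes and 9 of 14 immediate early genes fell. Of 24 endocytic and pattern recognition receptors 15 fell and 1 rose. Each of these 6 lists passed camera, and each call was lost with an estimated correlation (adjusted p = 0.0806 to 0.122). Ifit3 and Oasl2, both interferon-induced antiviral genes, rose by 3.53 ± 0.12 and 3.99 ± 0.16 on the log2 scale (SE, n = 2 per group; limma adjusted p = 5.76e-05 and 8.36e-05). The co-stimulatory genes Cd40 and Cd86, which help dendritic cells to activate T cells, rose by 2.47 ± 0.12 and 2.19 ± 0.11 (adjusted p = 0.000103 and 0.000125). The 4 probes of Cd40 gave 0.30 to 2.52 and the 3 of Ifit3 gave 0.43 to 3.53. C1qb, a complement subunit made by macrophages, had a log2 change of -5.67 ± 0.13, and the mannose receptor gene Mrc1 one of -4.12 ± 0.11 (adjusted p = 3.68e-05 for each). Of 7897 genes, 1723 rose and 1423 fell.

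The largest rises belonged to Thy1, a surface glycoprotein (4.63 ± 0.11), the transcription factor Msc (4.36 ± 0.32) and Cyp4a12a, a fatty acid hydroxylase (4.15 ± 0.15). Next came Oasl2, the myeloid precursor gene Ms4a3 (3.64 ± 0.34), Ifit3, cyclin D2 (Ccnd2, 3.40 ± 0.17) and Oas2, an antiviral synthetase (3.21 ± 0.11). Mgarp, a mitochondrial protein, was at least 64.6-fold lower after ROS, where it was not above background. The other largest falls were in the immediate early genes Fos (-6.30 ± 0.17) and Egr1 (-5.07 ± 0.17) and the complement genes C1qb and C1qc (-5.06 ± 0.13). They also included the oxygen-sensing hydroxylase Egln3 (-4.90 ± 0.20), the phospholipid transfer protein Pltp (-4.85 ± 0.15) and the gluconeogenic enzyme Fbp1 (-4.74 ± 0.33). The second Pltp probe gave -2.78. Msc, Cyp4a12a and Ms4a3 were above background on 1 of the 2 unstimulated arrays, and Fbp1 on 1 of the 2 ROS arrays. With the dim array set at its detection level, Msc, Cyp4a12a and Ms4a3 were at least 18.9-fold, 16.6-fold and 11.4-fold higher and Fbp1 at least 25.3-fold lower. Adjusted p-values for these genes ran from 3.68e-05 (Thy1) to 0.000779 (Ms4a3).

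Of 31 measured interferon genes 25 rose, 0 fell and 6 did not pass after ROS (27 rose adjusted over the list alone). Irf7, the transcription factor that amplifies interferon production, rose by 3.03 ± 0.17. The list passed camera at adjusted p = 1.32e-12, and the call was lost at adjusted p = 0.0806 with an estimated correlation. In the maturation list 17 of 23 genes rose and 0 fell (17 and 1 adjusted over the list alone), among them Fscn1, which bundles actin in mature dendritic cells (2.67 ± 0.12), and Slamf1 (2.36 ± 0.17). That list had a camera adjusted p = 2.75e-06 and an adjusted p = 0.0806 with an estimated correlation. Cd80 rose by 1.95 ± 0.23 (adjusted p = 0.00166). The lymph node homing receptor Ccr7 had a log2 change of 0.93 ± 0.29 (adjusted p = 0.0455). That call ended under median scaling, with no scaling and with the replicate number as a block (adjusted p = 0.0534, 0.0751 and 0.0758). The log2 changes there were 0.81, 0.71 and 0.93. The call also ended without unstimulated 1, unstimulated 2 or ROS 2, where the log2 changes were 0.90, 0.96 and 0.57. Over all its alternatives the adjusted p ranged from 0.00487 to 0.181. MHC class I genes rose in 7 of 17 cases with 0 falls (8 rises adjusted over the list alone), led by their transactivator Nlrc5 (1.85 ± 0.11). Their list had a camera adjusted p = 0.00464 and an adjusted p = 0.351 with an estimated correlation.

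MHC class II genes went the other way after ROS: 13 of 16 fell and 0 rose (14 falls adjusted over the list alone). H2-Ab1, a chain of the class II molecule itself, changed by -1.79 ± 0.12 and H2-Aa by -2.54 ± 0.11 (adjusted p = 0.000262 and 9.87e-05), and H2-Ob, a regulator of peptide loading, was at least 6.66-fold lower. This list had a camera adjusted p = 1.96e-07 and an adjusted p = 0.122 with an estimated correlation. Among endocytic and pattern recognition receptors 15 of 24 fell and 1 rose (17 and 2 adjusted over the list alone), with the LPS co-receptor Cd14 at -3.86 ± 0.11. The receptors had a camera adjusted p = 1.22e-06 and an adjusted p = 0.0806 with an estimated correlation. Macrophage markers moved with these receptors, as 4 of 7 fell, including C1qb and C1qc, and 0 rose (camera adjusted p = 0.000912; adjusted p = 0.122 with an estimated correlation). Gpnmb, a macrophage marker with a high mean, had a log2 change of -0.30 ± 0.23 that did not pass (adjusted p = 0.349).

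In the glycolysis and hypoxia list 17 of 20 genes fell after ROS and 0 rose. They included the angiogenic factor Vegfa (-3.73 ± 0.15), the hypoxia-induced gene Ndrg1 (-3.48 ± 0.14) and Pdk1, a kinase that restrains pyruvate oxidation (-3.23 ± 0.13). The list had a camera adjusted p = 1.23e-10 and an adjusted p = 0.0806 with an estimated correlation. Immediate early genes fell in 9 of 14 cases with 0 rises (11 falls adjusted over the list alone), and the transcription factors Klf4 and Klf2 changed by -4.08 ± 0.21 and -3.97 ± 0.13. These genes had a camera adjusted p = 3.23e-06 and an adjusted p = 0.0806 with an estimated correlation. In the unfolded protein and integrated stress list 11 of 20 fell and 2 rose, led by Vldlr, a lipoprotein receptor (-3.80 ± 0.16), and Chac1, which degrades glutathione (-2.21 ± 0.12). Camera gave adjusted p = 0.00464 there, and adjusted p = 0.122 with an estimated correlation.

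Cell cycle genes rose with ROS in 17 of 26 cases and 1 fell. Among the largest were the replication licensing factors Mcm2 (1.85 ± 0.11) and Mcm5 (1.75 ± 0.12) and the thymidylate synthase gene Tyms (1.74 ± 0.11, with 4 probes from 0.36 to 1.74). The list had a camera adjusted p = 9.81e-05 and an adjusted p = 0.122 with an estimated correlation. Mast cell and basophil markers moved in the same direction, with 5 of 7 up and 1 down (6 and 1 adjusted over the list alone). Cpa3, a mast cell protease, rose by 2.48 ± 0.27, and Fcer1a, a chain of the IgE receptor, by 2.20 ± 0.15. The 3 probes of Cpa3 gave 0.70 to 2.48. Their list passed at camera adjusted p = 0.0240, with adjusted p = 0.201 with an estimated correlation.

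NRF2 targets, the genes of the oxidative stress response, did not pass camera as a list after ROS: 5 of 16 rose, 2 fell and 9 did not pass (adjusted p = 0.585). With fry, which does not compare a list with other genes, they passed at adjusted p = 0.00945, as did most lists, 21 of 26 in all. Nqo1, a quinone reductase, rose by 1.87 ± 0.12 and Gclm, a subunit of the enzyme that starts glutathione synthesis, by 1.01 ± 0.13 (adjusted p = 0.000228 and 0.00236). The heme oxygenase gene Hmox1 changed by -1.59 ± 0.24 (adjusted p = 0.0039). Antioxidant enzymes rose in 2 and fell in 5 of 18 cases (adjusted p = 0.144), with the secreted peroxidase Gpx3 at -2.38 ± 0.12. Heat shock genes rose in 8 and fell in 3 of 13 cases (adjusted p = 0.218). Hspa1a, an inducible chaperone, was at least 5.79-fold lower and the co-chaperone Stip1 rose by 1.44 ± 0.13. Cytokines and chemokines rose in 8 and fell in 5 of 27 cases (adjusted p = 0.605). Tnf rose by 2.15 ± 0.14 and the T cell attractant Ccl22 by 2.53 ± 0.15. Il1b changed by -1.62 ± 0.11, and Il6 had a log2 change of -0.11 ± 0.24 that did not pass (adjusted p = 0.760).

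The remaining lists did not pass camera after ROS. Members rose and fell in 6 and 3 of 17 p53 targets (7 and 3 adjusted over the list alone), 8 and 7 of 21 NF-kappaB feedback genes (9 and 7 adjusted over the list alone), and 3 and 5 of 12 inducible effector enzymes. They did so in 0 and 2 of 5 NADPH oxidase genes, 2 and 2 of 27 respiratory chain genes, 6 and 2 of 15 cholesterol synthesis genes (6 and 3 adjusted over the list alone), and 2 and 3 of 16 heme genes. Arg1, the arginase linked to alternative activation, changed by -3.32 ± 0.14. Among cell types the counts were 3 and 0 of 7 for type 1 and plasmacytoid dendritic cells, 5 and 9 of 16 for neutrophils (5 and 10 adjusted over the list alone), 2 and 0 of 5 for natural killer cells (2 and 1 adjusted over the list alone) and 1 and 2 of 6 for stromal cells (1 and 3 adjusted over the list alone). Lists with too few measured genes for a test gave 1 rise among 1 T and B cell gene, 2 rises among 3 erythroid genes and 0 changes among 2 sex-linked genes. Without the first or the second unstimulated array 1893 or 1908 genes changed, against 3146 with all arrays. Under median scaling, which shifted the median fold of all genes by -0.0933, 1360 genes rose and 1738 fell. With no scaling, a shift of -0.197, these were 1019 and 2088, and the means of all 11 lists that passed kept their signs under both.

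The second comparison asked what LPS changed over 18 h. All 31 interferon genes and 21 of 27 cytokine and chemokine genes rose, and 14 of 16 neutrophil genes and 22 of 26 cell cycle genes fell. These 4 lists passed camera, and each call was lost with an estimated correlation (adjusted p = 0.0876). Ifit3 rose by 8.58 ± 0.12 on the log2 scale and the master regulator Irf7 by 7.90 ± 0.17 (SE, n = 2 per group; limma adjusted p = 2.88e-06 and 5.31e-06). The chemokine Cxcl10, which attracts activated T cells, was at least 283-fold higher after LPS. The 3 probes of Ifit3 gave 5.42 to 8.58. Il6, Tnf and Il1b, the classical inflammatory cytokines, rose by 3.32 ± 0.24, 3.97 ± 0.14 and 2.76 ± 0.11 (adjusted p = 0.000153, 1.11e-05 and 1.67e-05). The neutrophil granule gene Ltf changed by -6.98 ± 0.11 (adjusted p = 2.88e-06), though its second probe gave -2.24. Of 7897 genes, 1950 rose and 2289 fell.

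The other largest rises after LPS were in the interferon-induced genes Ifit2 (7.80 ± 0.11), Rsad2 (7.72 ± 0.17) and Isg15 (at least 139-fold), and in the acute phase gene Saa3 (7.28 ± 0.18) and the neutrophil attractant Cxcl1 (6.40 ± 0.15). The other largest falls were in Selenbp1, a selenium-binding protein (-6.50 ± 0.39), and S100a9, a calcium-binding protein abundant in neutrophils (-6.00 ± 0.20). The granule gene Ngp (at least 34-fold lower), coagulation factor F13a1 (at least 35.2-fold lower), Egr1 (-5.54 ± 0.17), Mgarp (-5.49 ± 0.25) and the glycolytic enzyme Aldoc (-5.38 ± 0.30) were also among them. Selenbp1, Mgarp and Aldoc were above background on 1 of the 2 LPS arrays, and with the dim array at its detection level they were at least 77.5-fold, 44.2-fold and 34.9-fold lower. The second Ifit2 probe gave 6.28. Adjusted p-values for these genes ran from 2.88e-06 (Ifit2) to 6.70e-05 (Selenbp1).

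For the interferon list camera gave adjusted p = 1.66e-20, and adjusted p = 0.0876 with an estimated correlation. Of 27 cytokine and chemokine genes 21 rose and 2 fell, with Ccl12 at 5.05 ± 0.15 and Il12a, a subunit of interleukin 12, at least 23.9-fold higher (camera adjusted p = 2.32e-08; adjusted p = 0.0876 with an estimated correlation). Ccl12 was above background on 1 of the 2 unstimulated arrays, and at least 32-fold higher with the other at its detection level. Inducible effector enzymes rose in 10 of 12 cases and 1 fell (11 and 1 adjusted over the list alone). Among them Ch25h, which makes an antiviral oxysterol, rose by 5.09 ± 0.13 and the prostaglandin synthase Ptges by 4.56 ± 0.11. The enzymes had a camera adjusted p = 2.68e-05 and an adjusted p = 0.0876 with an estimated correlation. NF-kappaB feedback genes rose in 13 and fell in 2 of 21 cases, with the receptor gene Tlr2 at 2.44 ± 0.15 (camera adjusted p = 0.00073; adjusted p = 0.181 with an estimated correlation). In the unfolded protein and integrated stress list 11 of 20 rose and 4 fell, led by the stress-induced Nupr1 (3.66 ± 0.14) and Ddit3 (3.32 ± 0.11). Camera gave it adjusted p = 0.00653, and adjusted p = 0.130 with an estimated correlation. With no scaling between the arrays, the median of this list turned negative.

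MHC class I genes rose with LPS in 13 of 17 cases and 1 fell, including the class I heavy chains H2-K1 (2.82 ± 0.20) and H2-D1 (2.75 ± 0.16). Class I genes had a camera adjusted p = 1.97e-05 and an adjusted p = 0.154 with an estimated correlation. MHC class II genes fell in 11 of 16 cases and 0 rose, with the peptide loading gene H2-DMb2 at -4.38 ± 0.21, the class II transactivator Ciita at -3.60 ± 0.30 and H2-Ab1 at -0.64 ± 0.12 (camera adjusted p = 0.00155; adjusted p = 0.185 with an estimated correlation). H2-DMb2 was above background on 1 of the 2 LPS arrays, and at least 17.2-fold lower with the other at its detection level. The maturation list split, with 10 of 23 up and 6 down, and did not pass camera (adjusted p = 0.0635). It did pass under median scaling (adjusted p = 0.00464), with no scaling (0.000615), with no background correction (0.0317), on the authors' values (0.0432) and without the first unstimulated array (0.0469). Its mean log2 change was smaller under both scalings, at 0.38 with median scaling and 0.14 with no scaling against 0.81, and the median of all genes also moved down. Its adjusted p over all alternatives, fry and the estimated correlation included, ranged from 6.13e-05 to 0.185. Cd40 rose by 4.69 ± 0.12 and Cd86 by 1.99 ± 0.11 (adjusted p = 5.31e-06 and 5.28e-05). The 4 Cd40 probes gave 2.87 to 5.02 and the 3 Cd86 probes 1.59 to 5.04. Cd80 and Ccr7 had log2 changes of 0.56 ± 0.23 and -0.65 ± 0.29 that did not pass (adjusted p = 0.0841 and 0.105).

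Neutrophil and granulocyte precursor genes fell with LPS in 14 of 16 cases and 1 rose. This list had a camera adjusted p of 9.69e-07 and an adjusted p = 0.0876 with an estimated correlation. S100a8, the partner of S100a9, changed by -3.65 ± 0.12, while Chil3, a chitinase-like protein of myeloid cells, had a log2 change of -0.18 ± 0.11 that did not pass (adjusted p = 0.200). The 3 probes of Chil3 gave -1.08 to -0.18. Cell cycle genes fell alongside the neutrophil genes in 22 of 26 cases and 1 rose. The mitotic genes Cdc20 and Top2a were at least 8.82-fold and 9.58-fold lower and Plk1, a mitotic kinase, changed by -3.11 ± 0.17 (camera adjusted p = 1.43e-07; adjusted p = 0.0876 with an estimated correlation). These falls were measured on the arrays with the lowest raw signal. Stromal markers rose in 4 of 6 cases with 0 falls (5 rises adjusted over the list alone), with the proteoglycan gene Dcn at 4.55 ± 0.15, and their list had camera adjusted p = 0.00559 and adjusted p = 0.130 with an estimated correlation.

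Glycolysis and hypoxia genes fell with LPS in 13 and rose in 3 of 20 cases, with Egln3 at -4.77 ± 0.20 and the glucose transporter Slc2a3 at -3.65 ± 0.16. Camera gave them adjusted p = 0.00559, and adjusted p = 0.130 with an estimated correlation. The call also ended under median scaling (adjusted p = 0.109) and with no scaling (0.208), and the adjusted p over all alternatives ranged from 0.000137 to 0.208. The mean log2 change of the list was -1.08, and it was larger in size, -1.44 and -1.68, under these settings, which moved the median of all genes by -0.469 and -0.707. Respiratory chain genes fell in 15 of 27 cases with 0 rises, with the cytochrome c oxidase subunit Cox4i1 at -1.32 ± 0.21 (camera adjusted p = 0.000209; adjusted p = 0.0876 with an estimated correlation). Of 15 cholesterol synthesis genes 8 fell and 1 rose, and Sqle, a rate-limiting enzyme of the pathway, changed by -2.09 ± 0.15 (camera adjusted p = 0.00559; adjusted p = 0.130 with an estimated correlation). Immediate early genes fell in 9 of 14 cases with 0 rises (11 falls adjusted over the list alone), with Klf2 at -4.94 ± 0.13 and Fos at -3.62 ± 0.17. They had a camera adjusted p = 0.00116 and adjusted p = 0.122 with an estimated correlation.

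NRF2 targets rose in 6 and fell in 3 of 16 cases after LPS (7 and 3 adjusted over the list alone; camera adjusted p = 0.132). The largest changes in size were rises of Sqstm1 (2.34 ± 0.15) and Slc7a11 (2.31 ± 0.12; limma adjusted p = 7.95e-05 and 4.52e-05). Nqo1 rose by 1.62 ± 0.12 (adjusted p = 0.00016), while Hmox1 and Gclm had log2 changes of -0.41 ± 0.24 and -0.14 ± 0.13 that did not pass (adjusted p = 0.193 and 0.395). Antioxidant enzymes rose in 3 and fell in 10 of 18 cases, with the mitochondrial superoxide dismutase Sod2 at 2.00 ± 0.17 and the glutathione peroxidase Gpx1 at -1.43 ± 0.11. Endocytic and pattern recognition receptors rose in 11 and fell in 9 of 24 cases (12 and 11 adjusted over the list alone), from Clec4e, a receptor for microbial glycolipids (5.08 ± 0.13), to Mrc1 (-3.19 ± 0.11). Rises and falls numbered 2 and 4 of 13 heat shock genes, 4 and 5 of 17 p53 targets, 2 and 1 of 5 NADPH oxidase genes, and 3 and 6 of 16 heme genes. They numbered 1 and 4 of 7 type 1 and plasmacytoid dendritic cell genes, 2 and 3 of 7 macrophage genes, 2 and 5 of 7 mast cell and basophil genes and 1 and 2 of 5 natural killer cell genes, and none of these lists passed camera. Untested lists gave 1 fall of 1 T and B cell gene, 2 rises and 1 fall of 3 erythroid genes and 0 changes of 2 sex-linked genes. The balance of rises and falls rested on the scaling. Under median scaling, which shifted the median fold of all genes by -0.469, 869 genes rose and 4180 fell. With no scaling, a shift of -0.707, 615 rose and 5184 fell. The means of all 14 lists that passed kept their signs under both.

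**Figure D1:**
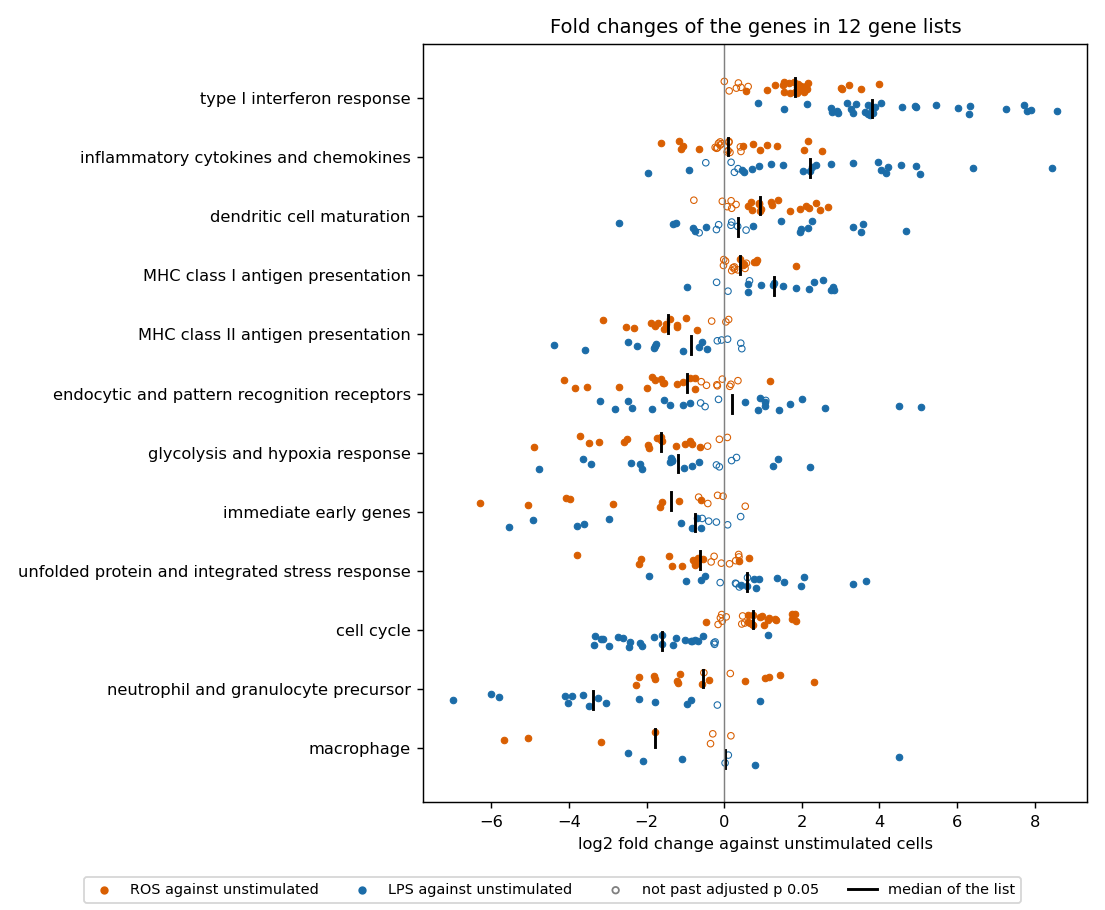
Log2 fold changes (x axis) of the measured genes of 12 lists (y axis), ROS against unstimulated in orange and LPS against unstimulated in blue; each point is 1 gene, filled where its adjusted p is under 0.05, and black bars are list medians. The interferon list has a median of 1.82 with ROS and 3.80 with LPS, and the neutrophil list one of -0.54 with ROS and -3.38 with LPS.

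The third comparison set LPS directly against ROS. All 31 interferon genes, 21 of 27 cytokine and chemokine genes and 14 of 20 unfolded protein and integrated stress genes were higher after LPS than after ROS, and 25 of 26 cell cycle genes and 12 of 16 neutrophil genes were lower. These 5 lists passed camera, and each call was lost with an estimated correlation (adjusted p = 0.0851 to 0.0872). Cxcl10 and Cxcl1 were higher after LPS by 7.09 ± 0.16 and 5.99 ± 0.15 on the log2 scale (SE, n = 2 per group; limma adjusted p = 7.26e-06 for each). Prg2, the eosinophil major basic protein, and Ear6, an eosinophil-associated ribonuclease, differed by -6.17 ± 0.13 and -5.42 ± 0.13 (adjusted p = 7.26e-06 for each). Of 7897 genes, 1963 were higher and 2438 lower after LPS than after ROS.

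Ms4a8a, a membrane protein, and Fam110c were at least 35.1-fold and 45.9-fold higher after LPS than after ROS. Nupr1 differed by 5.80 ± 0.14, Ifit2 by 5.72 ± 0.11, Rsad2 by 5.58 ± 0.17 and Saa3 by 5.44 ± 0.18. On the other side, Nrep and Asb2 were at least 30.6-fold and 27.9-fold lower after LPS, and the granule proteases of neutrophil precursors Prtn3 and Ctsg at least 25.4-fold and 22.1-fold lower. S100a9 differed by -5.48 ± 0.20 and Ltf by -5.21 ± 0.11, with -0.30 for the second Ltf probe. Adjusted p-values for these genes ran from 7.26e-06 (Nupr1) to 1.67e-05 (Ms4a8a).

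Among the interferon genes Ifit3 was higher after LPS than after ROS by 5.05 ± 0.12 and Irf7 by 4.87 ± 0.17 (camera adjusted p = 4.78e-16; adjusted p = 0.0851 with an estimated correlation). Of 27 cytokine genes 21 were higher and 2 lower (22 and 3 adjusted over the list alone), including Il1b (4.39 ± 0.11), Il6 (3.43 ± 0.24) and Tnf (1.82 ± 0.14). Cytokines had a camera adjusted p = 6.51e-08 and an adjusted p = 0.0851 with an estimated correlation. Among effector enzymes 11 of 12 were higher and 1 lower; Nos2, the inducible nitric oxide synthase, was at least 10.3-fold higher (camera adjusted p = 5.72e-06; adjusted p = 0.0851 with an estimated correlation). Of 20 unfolded protein and integrated stress genes 14 were higher and 2 lower (15 and 2 adjusted over the list alone), with Chac1 at 4.18 ± 0.12 and Ddit3 at 3.40 ± 0.11. That list had a camera adjusted p of 0.000101 and an adjusted p = 0.0851 with an estimated correlation. NF-kappaB feedback genes were higher in 14 and lower in 3 of 21 cases, with Socs3, an inhibitor of cytokine signalling, at 3.26 ± 0.11 (camera adjusted p = 0.00419; adjusted p = 0.235 with an estimated correlation). MHC class I genes were higher in 11 and lower in 1 of 17 cases (camera adjusted p = 0.0021; adjusted p = 0.235 with an estimated correlation).

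Endocytic and pattern recognition genes were higher after LPS in 13 of 24 cases and lower in 2 (14 and 2 adjusted over the list alone), with Cd14 at 5.28 ± 0.11 and the Fc receptor Fcgr1 at 4.34 ± 0.13. Camera gave the receptors adjusted p = 0.000164, and adjusted p = 0.0851 with an estimated correlation. Macrophage markers went with them, 5 of 7 higher and 1 lower, including C1qc (3.97 ± 0.13; camera adjusted p = 0.003; adjusted p = 0.109 with an estimated correlation). Stromal markers were higher in 5 of 6 cases and lower in 1, with Dcn at 5.19 ± 0.15 (camera adjusted p = 0.019; adjusted p = 0.169 with an estimated correlation). Glycolysis and hypoxia genes were higher after LPS in 9 of 20 cases and lower in 2, with Vegfa at 4.04 ± 0.15 and the hypoxia regulator Hif1a at 2.64 ± 0.18 (camera adjusted p = 0.00523; adjusted p = 0.109 with an estimated correlation).

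Cell cycle genes were lower after LPS than after ROS in 25 of 26 cases and higher in 0, with Plk1 at -4.04 ± 0.17 and Top2a at least 14.6-fold lower (camera adjusted p = 6.60e-10; adjusted p = 0.0851 with an estimated correlation). Neutrophil genes were lower in 12 of 16 cases and higher in 2 (camera adjusted p = 0.000248; adjusted p = 0.0872 with an estimated correlation). Cholesterol synthesis genes were lower in 11 of 15 cases and higher in 1, with Fdps, the farnesyl diphosphate synthase, at -2.88 ± 0.11. Their camera adjusted p was 0.003, with adjusted p = 0.109 with an estimated correlation. Respiratory chain genes were lower in 14 of 27 cases and higher in 0, with Ndufa4 at -1.44 ± 0.12 (camera adjusted p = 0.00307; adjusted p = 0.109 with an estimated correlation).

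The maturation genes differed in both directions, 8 of 23 higher and 11 lower after LPS (camera adjusted p = 0.606). Cd40 was higher by 2.23 ± 0.12, whereas Fscn1 (-3.47 ± 0.12), Cd80 (-1.39 ± 0.23) and Ccr7 (-1.58 ± 0.29) were lower (adjusted p = 3.57e-05, 1.14e-05, 0.00325 and 0.00478). Cd86 had a log2 difference of -0.20 ± 0.11 that did not pass (adjusted p = 0.169), and its probes went apart, from -0.37 to 3.35. H2-Ab1 was higher after LPS by 1.14 ± 0.12, in a class II list with 7 of 16 genes higher and 3 lower (adjusted p = 0.412). Hmox1 was higher by 1.18 ± 0.24 and Gclm differed by -1.15 ± 0.13 (adjusted p = 0.00708 and 0.000707), and Nqo1 had a difference of -0.25 ± 0.12 that did not pass (adjusted p = 0.128).

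No other list passed camera between LPS and ROS. Genes higher and lower after LPS numbered 6 and 4 of 16 NRF2 targets, 4 and 6 of 18 antioxidant enzymes, 2 and 7 of 13 heat shock genes (2 and 8 adjusted over the list alone), 3 and 10 of 17 p53 targets, and 7 and 4 of 14 immediate early genes (7 and 5 adjusted over the list alone). They numbered 2 and 0 of 5 NADPH oxidase genes and 4 and 6 of 16 heme genes. Cell type counts were 1 and 5 of 7 for type 1 and plasmacytoid dendritic cells, 2 and 5 of 7 for mast cells and basophils, and 1 and 2 of 5 for natural killer cells. Untested lists gave 0 and 1 of 1 T and B cell gene, 1 and 1 of 3 erythroid genes and 0 and 0 of 2 sex-linked genes. Under median scaling, which shifted the median of all genes by -0.378, 1111 genes were higher and 3923 lower. With no scaling, a shift of -0.513, they numbered 926 and 4381. The means of all 14 lists that passed kept their signs under both.

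**Figure D2:**
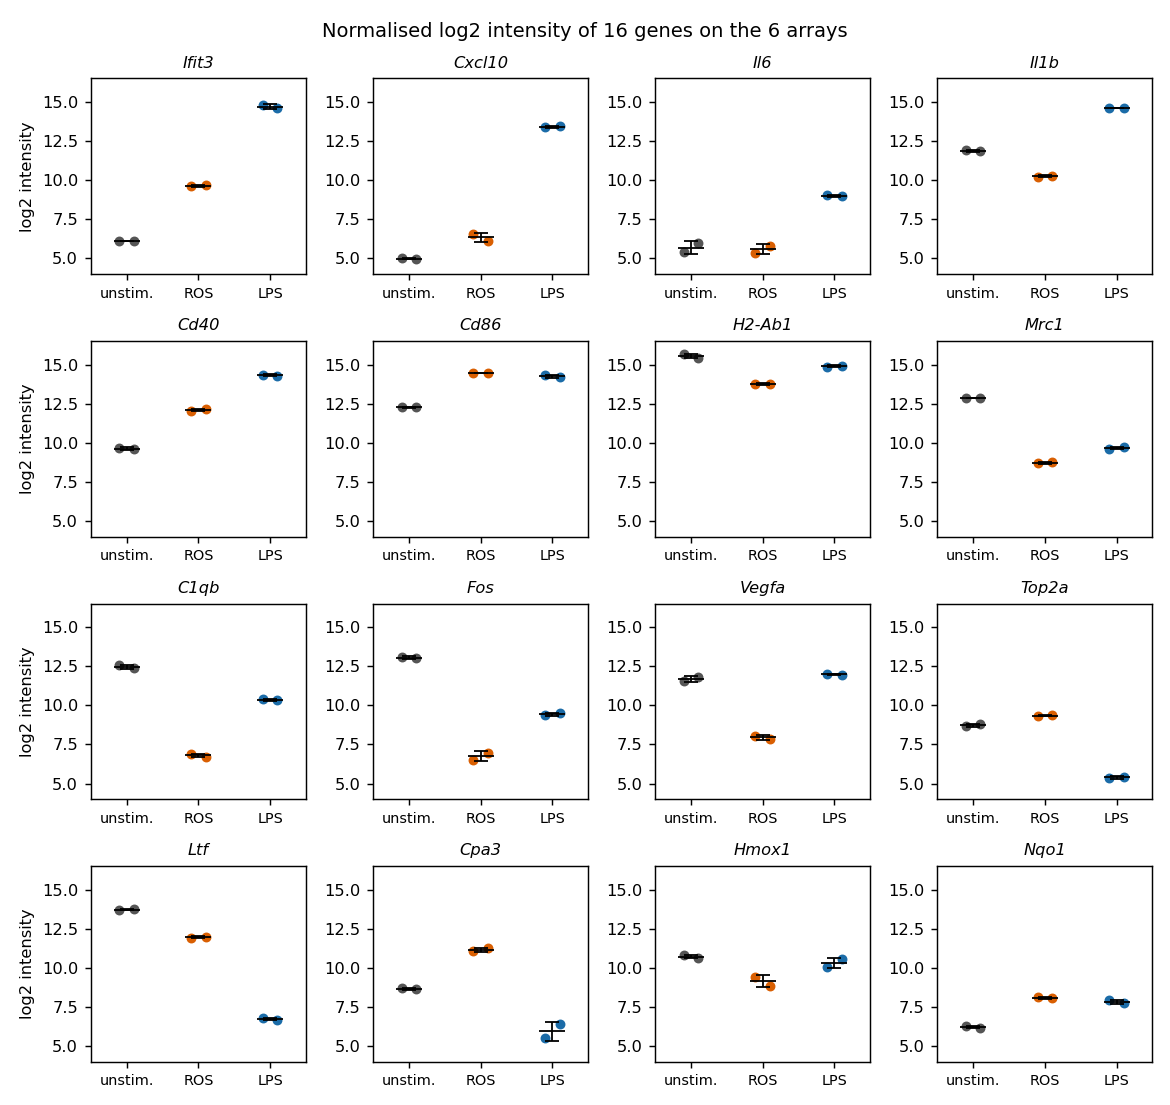
Normalised log2 intensity (y axis) of 16 genes on the unstimulated, ROS and LPS arrays (x axis); each dot is 1 array, and the black marks show the mean and SD of the 2 arrays of a group. Ifit3 rises in both treated groups, Il1b goes down with ROS and up with LPS, and Cpa3 goes up with ROS and down with LPS.

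The last comparison asked how far the responses to ROS and LPS coincided. Ifit3, Irf7, Oasl2 and Cd40 rose in both, and Egr1, Fos, Mgarp and Mrc1 fell in both. Across 7897 genes the log2 fold changes correlated at r = 0.318 (Spearman 0.258). Genes are not independent replicates. Both comparisons use the same unstimulated arrays, and 1000 simulations of unchanged groups against those arrays gave a mean r of 0.5004. That value follows from the shared arrays alone, whatever the treatments do, so the observed r cannot be judged against it. The covariance was 0.274 against a simulated 0.0163, a difference of 0.258. Rises shared by both treatments numbered 659 genes, where independent lists of these sizes would share 425, and shared falls numbered 744, against 412. Genes that rose with ROS and fell with LPS numbered 400, against 499 for independent lists, and those that fell with ROS and rose with LPS numbered 246, against 351. Each treatment cannot be given a pair of unstimulated arrays of its own, so part of the excess of shared calls may come from the shared arrays. With 1 unstimulated array for each treatment, and so none shared, r was 0.290 or 0.298, where the highest of 1000 simulations of unchanged groups was 0.0533.

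**Figure D3:**
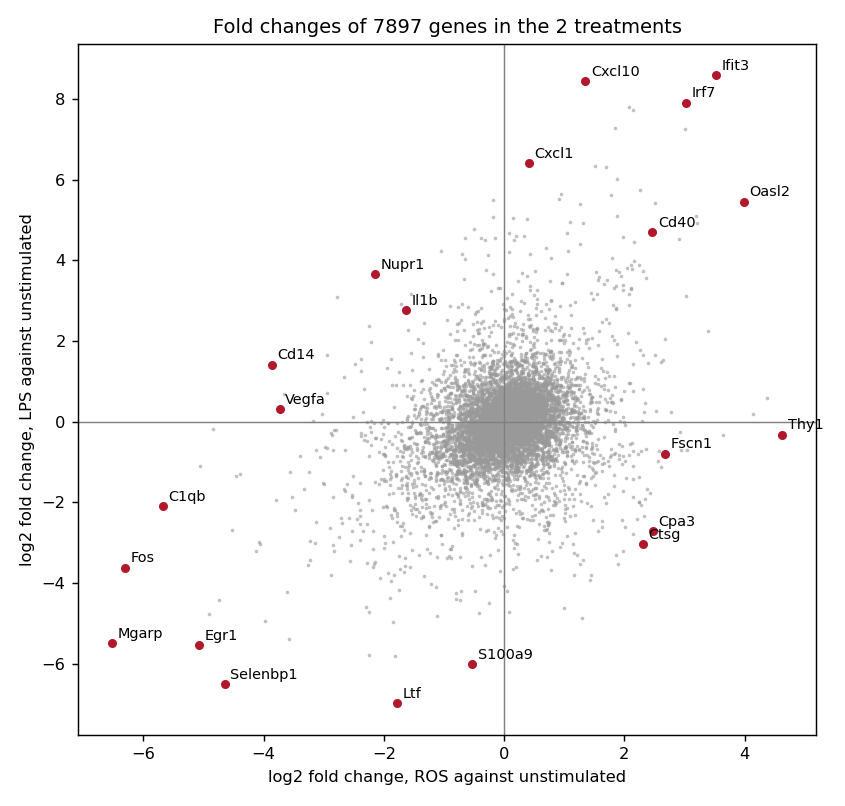
Log2 fold change with LPS (y axis) against that with ROS (x axis), both against the unstimulated arrays; each grey point is 1 of 7897 genes and named genes are red. Ifit3, Irf7 and Oasl2 lie at the upper right, Mgarp, Egr1 and Selenbp1 at the lower left, and Il1b, Cd14, Cpa3 and Ctsg in the quadrants where the treatments oppose each other.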

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

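The setting with no normalization between arrays and the crossed pairing were chosen after seeing the data; all other alternatives were planned. Requiring an absolute log2 fold change of at least 1 left 1092 genes for ROS against unstimulated, 1764 for LPS against unstimulated and 2058 for LPS against ROS; this adds a condition and can only remove genes. Leaving out each array in turn, with the lone array of a group taken to vary like the others, gave 1893 to 3291 genes for ROS against unstimulated, of which the lowest values came without an unstimulated array; fewer samples carry the test there. It gave 3113 to 4093 and 3524 to 4072 genes for the other comparisons. All other settings kept the counts of changed genes within 1.5 times, but not the balance of directions given with each comparison. Under median scaling 2722 of 3146, 3156 of 4239 and 3543 of 4401 calls passed again in the same direction. Another 0, 1 and 0 were called the opposite way, and the rest did not pass. With no normalization between arrays 2421, 2904 and 3364 passed again in the same direction, with 0, 99 and 0 opposite.

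With an estimated correlation 0 lists passed in each of the 3 comparisons, against 11, 14 and 14 with the preset one. The estimate was 0.066 for the interferon list but -0.0129 for the glycolysis and hypoxia list, below the preset 0.01. For the latter list, camera p before adjustment went from 9.48e-12 to 0.00502 in ROS against unstimulated. That loss thus does not come from correlated genes. Estimates were also negative for other lists, such as maturation (-0.0289), immediate early genes (-0.0561) and neutrophils (-0.033). They lay above the preset for others, such as cytokines (0.0343), the cell cycle (0.0347) and MHC class I (0.143). The estimated version rests on 3 residual degrees of freedom and the preset one on the number of genes. The loss in every list thus cannot be read as correlation between genes alone. With fry, which does not compare a list with other genes, 21, 23 and 24 passed. Across planned and added scalings and background settings 11, 14 to 16 and 14 lists passed. The correlation of the fold changes of ROS and LPS was 0.318; it was 0.325 with no background correction, 0.334 with median scaling, 0.328 on the authors' values, 0.338 with the strict detection filter, 0.334 with no normalization between arrays, and 0.306 to 0.331 with each array left out. Acta2 turned to -0.55 for LPS against unstimulated with no normalization between arrays (adjusted p = 0.0121), against 0.25 in the main fit, which did not pass. That setting shifted the median fold of all genes by -0.707 in this comparison.

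The replicate numbers did not pair the arrays: deviations of same-numbered arrays correlated at -0.104, 0.021 and -0.0232. With the replicate block 2816, 4054 and 4175 genes changed, r was 0.321, no list call changed, and of 340 folds of named genes 336 kept their side of the threshold; Ccr7 with ROS, at 0.93, did not (adjusted p = 0.0758). With the ROS numbers crossed, 3012, 4215 and 4351 genes changed. Over all arrays left out in turn, 1994 folds of named genes kept their side of the threshold, 43 lost their call and 3 gained one. Genes near background can be read only as bounds, and the LPS arrays, with the lowest signal, detected the fewest probes.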

Other observations

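The genes of the first 2 paragraphs were picked after their values were seen. The tests of candidate explanations in the paragraphs after them were chosen only after the results were seen. The list calls repeated there under planned settings were not. Some genes moved in opposite directions with the stimuli. Cpa3, Fcer1a and Ctsg, granule and receptor genes of mast cells and granulocyte precursors, rose with ROS by 2.48 ± 0.27, 2.20 ± 0.15 and 2.30 ± 0.11 on the log2 scale (SE, n = 2 per group). After LPS, Cpa3 changed by -2.71 ± 0.27, and Fcer1a and Ctsg were at least 3.83-fold and 4.46-fold lower. The 3 probes of Cpa3 gave 0.70 to 2.48 with ROS and -2.80 to -0.28 with LPS. Mycl, a transcription factor of the Myc family, rose with ROS by 2.32 ± 0.18 and was at least 4.66-fold lower after LPS. Eno3, the muscle enolase, rose by 2.28 ± 0.13 with ROS and changed by -2.07 ± 0.13 with LPS.

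In the other direction, the stress genes Nupr1 and Chac1 changed by -2.14 ± 0.14 and -2.21 ± 0.12 with ROS and rose by 3.66 ± 0.14 and 1.97 ± 0.12 with LPS. Thbs1, a matrix glycoprotein, changed by -1.72 ± 0.18 with ROS and rose by 2.92 ± 0.18 with LPS, and Pmp22 changed by -2.95 ± 0.19 and rose by 1.66 ± 0.19. Cox6a2, a subunit of cytochrome c oxidase, changed by -2.25 ± 0.12 and rose by 2.37 ± 0.12.

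Of 31 interferon genes 25 rose with ROS. Mixing of RNA or cells from the LPS wells into the ROS samples would move every gene by 1 common share of the distance from the unstimulated to the LPS level on the linear scale. The first test compared the share over 21 cytokine genes with that over 31 interferon genes and left mixing open, since the upper quartile of the cytokine genes, 10.6%, was not below the lower quartile of the interferon genes, 3.51% (medians 0.397% and 12.6%). A second test, added after that outcome, took the share over the 25 interferon genes that rose. Its upper quartile was 5.40 and 5.97 times the lower one in the ROS arrays, with a median difference between those arrays of 0.990 percentage points. This argues against mixing as the whole of the rise. Shares also differ between probes of 1 gene, which the test did not take into account. The 2 Oasl2 probes gave log2 changes of 3.26 and 3.99 with ROS, and 5.65 and 5.45 in the same order with LPS. A trace of LPS cannot be told apart from an effect of ROS, because of 34 cytokine and NF-kappaB genes that rose with LPS 12 rose, 8 fell and 14 did not pass with ROS; a response to ROS itself may also account for the rise and was not tested.

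Of 20 glycolysis and hypoxia genes 13 fell in both treated groups, and of 14 immediate early genes 7; 3 glycolysis and hypoxia genes rose with LPS, and the LPS call of that list was lost under median scaling, with no scaling and with an estimated correlation (adjusted p = 0.109, 0.208 and 0.130). A candidate explanation is a state of the unstimulated wells alone, for the glycolysis and hypoxia genes and for the immediate early genes. It would leave ROS and LPS at the same level. Of the 7 immediate early genes that fell in both comparisons, 6 differed between LPS and ROS. Klf4 was among the 6, and it lost that call with no normalization between arrays. Such differences were common, as 4401 of all 7897 genes differed between LPS and ROS. They argue against a state of the unstimulated wells as the whole cause for the genes that differed, but not as a part of it. Among the 17 glycolysis and hypoxia genes that fell in either comparison 9 differed, 7 of them higher and 2 lower after LPS. Of the 13 that fell in both, 5 differed, which such a state alone would not give, and 8 had no called difference. The 95% interval of 1 of these 8 lay within 0.5 log2 units of 0. For the glycolysis and hypoxia list as a whole, and for Egr1 among the immediate early genes, a state of the unstimulated wells and a response common to the treatments cannot be told apart, for want of a further control group. The same holds for part of the fall of the other immediate early genes.

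Of 16 neutrophil genes 14 fell and 1 rose with LPS, a list call lost with an estimated correlation (adjusted p = 0.0876). The scaling between arrays is unlikely as the cause, because with no scaling the median of the list was -3.66 or lower in each of the 4 pairs of an LPS and an unstimulated array, where the median of all genes was between -0.851 and -0.666. Fewer granulocyte precursors in the LPS wells stay open and cannot be told apart from lower expression per cell. Of the 16 members 7 lay within 1 log2 unit of the list median of -3.38, with folds from -6.98 (Ltf) to 0.92 (Lcn2). Among members above background on the arrays of both groups, S100a9 changed by -6.00, S100a8 by -3.65 and Chil3 by -0.18. Such a spread argues against 1 common factor for all members, but not against fewer precursors as a part of the fall. Ngp, Prtn3 and Ctsg were not above background after LPS, so their falls may be larger than fitted. Part of the spread may come from the probes, as the second Ltf probe gave -2.24. An effect of LPS on transcription in these cells was not tested.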
